A study of Drosophila melanogaster with 5 samples.

How the data were processed

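CUT&RUN with a rat antibody against MLE was performed on permeabilised female embryos, with paired-end reads of 150 bp per the labels. The 5 libraries were 2 from control embryos at 0-2 h, 2 from control embryos at 2-4 h and 1 from clampRNAi embryos at 0-2 h. Groups and replicate numbers came from the sample titles. Per the series' design text, embryos came from several batches of crosses and timed egg-layings. Nothing in the labels says which library came from which batch, so replicates may share material. The permutation test of X shares by stage measures only the spread between these libraries. All other p-values come from peaks, regions or genes and measure no spread between libraries.

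The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.40, Bowtie2 2.4.4, SEACR 1.3, deepTools and the dm6 assembly, without roles or order. SEACR calls peaks from blocks of continuous coverage. Each deposited list gives, per peak, the authors' total signal (summed coverage) and maximum signal and the part of the peak with that maximum. The layout is that of SEACR, the values are whole numbers, and there was 1 list per library. The control track, the threshold and any scaling to the yeast spike-in DNA named in the extraction protocol are not given in the sources used here. Sequencing depth is unknown, so signal was not compared as a measured difference between libraries. It was used to rank peaks within a list as a percentile of total signal, and ranks from lists of different lengths show no change. Maximum signals are quoted as the authors' values. Intervals cover counting error over peaks or regions only, and no spread between libraries. Separately, reads without molecular identifiers are not independent molecules.

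Covered length was 294.9 kb and 587.6 kb in the 0-2 h controls, 112.6 kb and 4337 kb in the 2-4 h controls and 159.97 kb after clampRNAi, and the mean signal per covered base was 144, 582, 289, 107 and 203 in the same order. Peaks narrower than the read length made up 56.7%, 56.8%, 70.8%, 6.86% and 67.1% of the lists. The 10 peaks of highest total signal held 25.0%, 58.3%, 45.6%, 57.7% and 56.1% of each list's summed signal.

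Genes came from a RefSeq gene table of the Release 6 plus ISO1 MT assembly, which is the assembly that dm6 names. It gave gene extents without strand, exons or sequence, and 17673 of its genes lay on the main arms. The plan set before the data were examined was changed where it needed those. Motif tests were not run, promoter, UTR, exon and intron classes were replaced by the distance to either annotated gene end, a gene's region was its extent widened by 500 bp on both sides, and regions were named by the nearest gene extent, protein-coding first, instead of the nearest transcription start. The length of an arm was the largest coordinate seen on it in the gene table or the lists. Coordinates are 1-based on dm6.

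Peaks of the 5 lists, on all contigs, sharing at least 1 bp were merged into regions, each called or not in each library. Overlap of lists and position relative to genes (by the midpoint of the maximum) were tested against 1000 random placements of the same intervals on the same arm, a permutation of peak positions, two-sided. The X share was tested against X's share of arm length by an exact two-sided binomial test. Genes with a peak were counted for 16 lists fixed before the data were examined, against 10000 random lists matched on length decile and coding type, a permutation of genes within strata, two-sided. P-values were adjusted by Benjamini-Hochberg within each family of tests, with a threshold of 0.05. Wilson intervals were used for X shares and Clopper-Pearson intervals for other shares, at 95%. Peaks in 1 genome are not independent replicates, so these tests describe each library and not the condition. In the gene lists the symbols nos and SmG were not matched, and in the splicing factor list snf and snRNP-U1-A named the same gene.

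Genes named in the text were fixed by rule: roX1, roX2, Sxl, tra, msl-2, mle and Clamp; for each of 5 sets of regions the 6 main-arm regions of highest mean percentile over the libraries defining the set; and for each gene list up to 4 members with a peak in the most libraries. The sets were regions called in all 5 libraries, in both 0-2 h controls, in both 2-4 h and neither 0-2 h control, in both 0-2 h and neither 2-4 h control, and in both 0-2 h controls and not clampRNAi. The first and second sets gave the same 6 genes and the third was empty.

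On simulated lists of 595 peaks, 100 runs each, the X test called 4% of runs without an X excess and 100% of those with the X share raised to 30%. The overlap test called 1% of runs with independent lists and the gene-end test 5% of runs with random positions, and both called 100% of runs with a planted effect. For the list of 28 splicing factor genes the list test called 7% of runs without an effect and 100% with 6 genes given a peak. Lists of clustered genes, such as the histone genes, were not simulated. There 1 peak can cover several genes, which random lists do not reproduce, so the error rate for such lists was not measured.

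Alternatives set before the data were examined were the upper 50% of each list by total signal, lists of equal length, reciprocal overlap of 50%, merging within 500 bp, main arms only, placement on any arm, share of bases, share of genes as background, other distances to gene ends, gene ends in place of gene bodies and leaving out each control library. Peaks of at least 200 bp only, all contigs, removal of the centromeric ends, a background without rRNA genes and counting clustered genes as loci were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.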

Results

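MLE (Maleless) is an RNA helicase of the dosage compensation complex, which doubles transcription of the single X chromosome in male flies. Its positions on chromatin were mapped in Drosophila melanogaster female embryos by CUT&RUN, in which an antibody directs a DNA-cutting nuclease to the protein and the released fragments are sequenced. Control embryos came from mothers expressing an RNA hairpin against GFP, with 2 libraries from embryos aged 0-2 h, before the maternal-to-zygotic transition (the handover of gene control from maternal products to the embryo's genome), and 2 libraries from embryos aged 2-4 h, after it. A further library came from 0-2 h embryos whose mothers were depleted of CLAMP (clampRNAi), a zinc finger protein that binds GA-rich DNA. The crosses were built to give X-bearing sperm only. The number of reads behind each list is unknown, and each list was described by its peak number and the authors' signal, which was used to rank peaks within a list.

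The 5 lists held different numbers and kinds of peaks. The 0-2 h controls had 723 peaks in replicate 1 and 1247 in replicate 2, the 2-4 h controls 370 and 1589, and the clampRNAi library 493. Median peak width was 100 bp, 110 bp, 82 bp and 2190 bp in those 4 control libraries and 81 bp after clampRNAi. Peaks under 200 bp made up 60.0%, 60.5%, 73.2% and 7.49% of the control lists and 70.4% of the clampRNAi list. Most peaks of 2-4 h replicate 2 were broad, although 119 were under 200 bp. Their median maximum signal was 53 against 285 to 528 in the other 4 lists, and 30.6% of its peaks lay off the main chromosome arms (2L, 2R, 3L, 3R, 4 and X) against 11.1% to 17.7%.

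Among regions called in all 5 libraries, each of the leading 6 lay inside a gene. On the dm6 assembly these were in Glg1, which encodes a Golgi glycoprotein (3L, 21497986 to 21499896), spok, an ecdysone-synthesis cytochrome P450 gene (3R, 3344494 to 3345038), up, which encodes troponin T (X, 13593785 to 13594319), SK, a calcium-activated potassium channel gene (X, 5348316 to 5350562), gpp, which encodes the histone H3 lysine methyltransferase Grappa (3R, 6416546 to 6416876), and ctrip, a ubiquitin ligase gene (3R, 4800492 to 4802983). Their mean percentile of total signal over the 5 lists ran from 99.5 for Glg1 to 97.4 for ctrip. The peaks themselves were narrow in most libraries, at 140 to 148 bp for spok and 110 to 118 bp for gpp outside 2-4 h replicate 2, where they were 545 bp and 331 bp. Of 2263 merged regions, 274 were called in all 5 libraries and 1365 in 1 library. The strongest peaks were not all shared: of the 50 with most signal in 0-2 h replicate 2, 50 were called in 2-4 h replicate 2, 22 in 0-2 h replicate 1, 12 in 2-4 h replicate 1 and 17 after clampRNAi, while of the 50 of 0-2 h replicate 1 at least 49 were called in each other library.

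**Figure D1:**
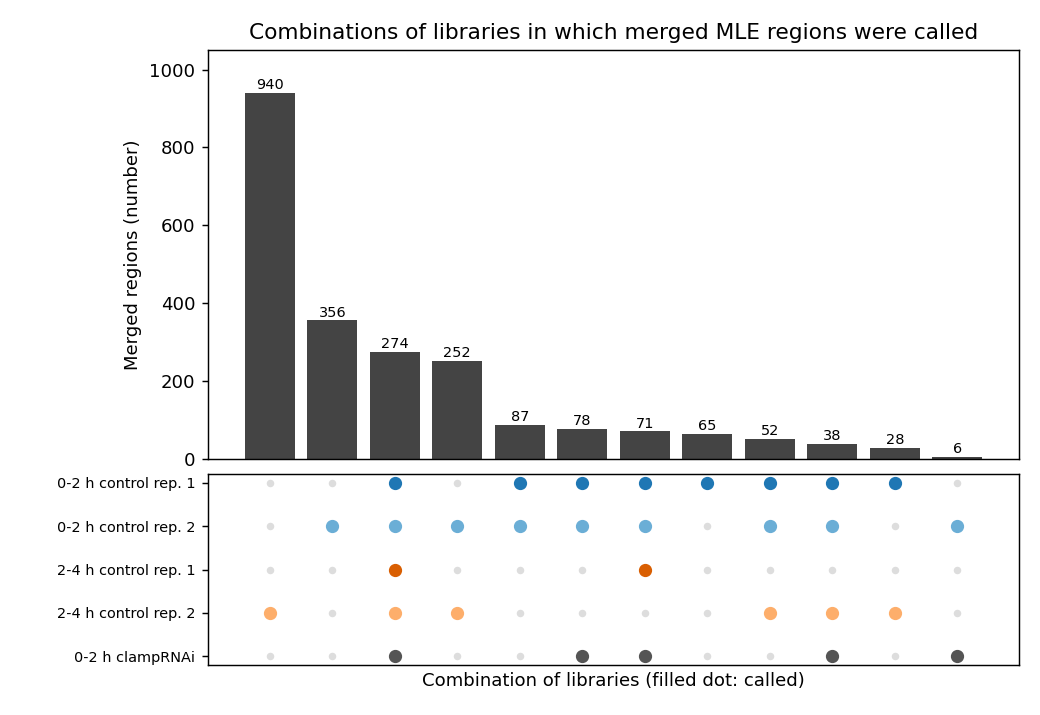
Number of merged MLE regions (bars, y axis) for each combination of the 5 libraries in which they were called (filled dots below), for combinations with at least 5 regions. The combination with most regions, 940, is 2-4 h replicate 2 alone, 274 regions were called in all 5 libraries, and no bar holds the 2-4 h controls without a 0-2 h control.

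Replicate lists overlapped far beyond chance, and some libraries of different stage or genotype overlapped more than replicates did. Of the main-arm peaks of 0-2 h replicate 1, 88.1% overlapped a peak of replicate 2 (0.646% in random placements), and 48.1% of replicate 2 peaks overlapped one of replicate 1. Of the 2-4 h replicate 1 peaks, 76.6% overlapped a peak of 2-4 h replicate 2, and 98.8% overlapped a peak of 0-2 h replicate 1. In the other direction, 22.3% of 2-4 h replicate 2 peaks overlapped a peak of 2-4 h replicate 1. Of the clampRNAi peaks, 98.2% and 99.3% overlapped peaks of 0-2 h replicates 1 and 2, while 71.4% and 39.5% of the peaks of those replicates overlapped a clampRNAi peak. For every ordered pair of libraries the permutation of peak positions gave an adjusted p = 0.001998, the smallest that the 1000 placements can give. Over covered bases, the Jaccard index was 51.1% between 2-4 h replicate 1 and clampRNAi, 19.7% between the 0-2 h replicates and 1.42% between the 2-4 h replicates. Overlap with the longer and wider lists was favoured by their size: with every list kept to 370 peaks the 76.6% became 24.3%, and with reciprocal overlap of 50% it became 20.7%. With peaks of at least 200 bp the 88.1% became 44.9%, and these tests compare positions in the genome, not conditions.

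The first comparison asked where MLE was found in female embryos before and after the maternal-to-zygotic transition. No region was called in both 2-4 h controls and in neither 0-2 h control. Of 276 regions called in both 2-4 h controls, 275 were called in both 0-2 h controls and 0 in neither. The short list of 2-4 h replicate 1 left little room for such regions, since 352 of its 356 regions were called in a 0-2 h control. A further 940 regions were called in 2-4 h replicate 2 alone, so the 0 does not show that no region gained MLE. In the other direction, 165 regions were called in both 0-2 h controls and in neither 2-4 h control, of 602 called in both 0-2 h controls. The 159 of them on the main arms had a median merged width of 90 bp and median percentiles of 24.5 and 45.5 in the 0-2 h lists, and 46.5% lay on X. Among them the highest ranked lay inside CG42674 (3L, 20192018 to 20192246), mamo, a zinc finger gene needed in the germ line (X, 13871519 to 13871640), stx (X, 10731597 to 10731658) and Rim, a synaptic active zone gene (3R, 17901261 to 17901393).

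Another pair of the leading 0-2 h regions lay outside protein-coding genes, 3704 bp from CG15140 on 2L and 2300 bp from CG15200 on X. Non-coding genes were not examined there. These 6 regions had mean percentiles of 52.2 to 55.4 over the 0-2 h lists, and all of them were also called in the clampRNAi list, at percentiles of 18.3 to 36.5. Of the whole set of 165 regions, 78 were called after clampRNAi and 87 were not. These counts of regions were not tested across libraries. With every list kept to 370 peaks both counts were 2. Leaving out a library removes a condition from the definition, which by itself favours a higher count: without 2-4 h replicate 1 the regions called after the transition alone were 941, and without 0-2 h replicate 1 those called before it alone were 527.

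Regions called in only 1 pair of the 4 control libraries divided them by replicate number more than by stage. Pairwise similarity was mixed. The Jaccard index over regions was 49.5% between the replicates 1 and 28.3% between the replicates 2. It was 45.7% between the 0-2 h controls and 16.5% between the 2-4 h controls. There were 254 regions called in both replicates 2 and in neither replicate 1, against 2 called in both replicates 1 and in neither replicate 2, and the crossed pairs held 28 and 2 regions alone. Within replicate 1, 349 regions were called at both ages, 349 at 0-2 h alone and 7 at 2-4 h alone. Within replicate 2, 620 were called at both ages, 601 at 0-2 h alone and 969 at 2-4 h alone. The direction of the stage difference in number of regions was therefore opposite in the 2 replicates, and with every list kept to its 370 peaks of highest total signal 306 regions were called at both ages within replicate 1 and 216 within replicate 2.

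Regions inside dco (a casein kinase gene of the circadian clock, 3R), Myo81F (a myosin gene, 3R) and Rab10 (a small GTPase gene, X) were called in both 0-2 h controls and ranked far apart in them. The dco peak had an authors' maximum signal of 149346 in 0-2 h replicate 2 and 219871 in 2-4 h replicate 2, against 220 in 0-2 h replicate 1, and was not called in 2-4 h replicate 1 or clampRNAi. It ranked at a percentile of 99.7 in both replicates 2 and of 30.7 in 0-2 h replicate 1. For the Myo81F peak the values were 120491 and 191016 against 233, and for Rab10 they were 96038 and 118929 against 157. These are values on scales of unknown depth, not measured differences between libraries.

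The second comparison asked whether MLE positions at 0-2 h depended on maternal CLAMP. Most regions called in both 0-2 h controls were also called with CLAMP depleted: 461 of 602, 76.6% (Clopper-Pearson 95% interval 73.0% to 79.9%). Among all 1221 regions of 0-2 h replicate 2 the share was 38.5%. The clampRNAi library added almost nothing, with 473 of its 476 regions called in a 0-2 h control. The regions inside Glg1, spok, up, SK, gpp and ctrip were all called after clampRNAi, at percentiles of 98.0 to 99.6. Of the regions on X, 193 of 245 were called after clampRNAi (78.8%), and of those on autosomal arms 220 of 267 (82.4%). The difference did not pass Fisher's exact test across regions (p = 0.315). Regions off the main arms were left out of that test. On the main arms alone 80.7% of 512 regions were called, above the 76.6% of all regions, so the share was lower off the main arms. Of the 141 regions not called, 99 lay on the main arms.

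The 141 regions not called after clampRNAi were of lower rank in the controls, at a median percentile of 22.1 in 0-2 h replicate 1 and 43.0 in replicate 2, against 66.1 and 69.8 for those called. Among the highest ranked of them, those on 3L lay between protein-coding genes. They were 10997 bp from CkIIalpha (23110959 to 23117955) and 16662 bp and 26382 bp from CG42598 (26387451 to 26388585 and 26395002 to 26400474). The other highest ranked regions lay inside dco, Myo81F and Rab10. All 6 were also called in 2-4 h replicate 2 and none in 2-4 h replicate 1, while of the whole set of 141 these libraries called 53 and 2.

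As a measure of how far replicates of the same genotype differed, 86.2% of the 0-2 h replicate 1 regions were called in replicate 2 and 49.3% of the replicate 2 regions in replicate 1. The clampRNAi library called 66.5% of the replicate 1 regions and 38.5% of the replicate 2 regions. These shares depend on list length: clampRNAi had 493 peaks and 0-2 h replicate 2 had 1247. A control library of the later stage with maternal CLAMP, 2-4 h replicate 1, called 57.6% of the 602 regions (53.6% to 61.6%). The clampRNAi group had 1 library, so no difference between conditions could be tested. With every list kept to 370 peaks, 0-2 h replicate 1 shared more regions with clampRNAi (317) than with 0-2 h replicate 2 (227). Replicate 2 shared 217 with clampRNAi. Of the 227 regions called in both 0-2 h controls, 93.0% were called after clampRNAi, with 16 regions not called.

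At the Clamp gene itself (2L, 22165720 to 22169143) MLE peaks were called in all 5 libraries. The strongest lay at percentiles of 98.3 and 81.7 in the 0-2 h controls, 95.1 and 63.4 in the 2-4 h controls and 99.8 after clampRNAi, where it spanned 22166663 to 22168320 with a maximum signal of 3075. In 0-2 h replicate 1 and 2-4 h replicate 1 it began at 22166666. These lists do not measure Clamp RNA, so the depletion was not checked.

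**Figure D2:**
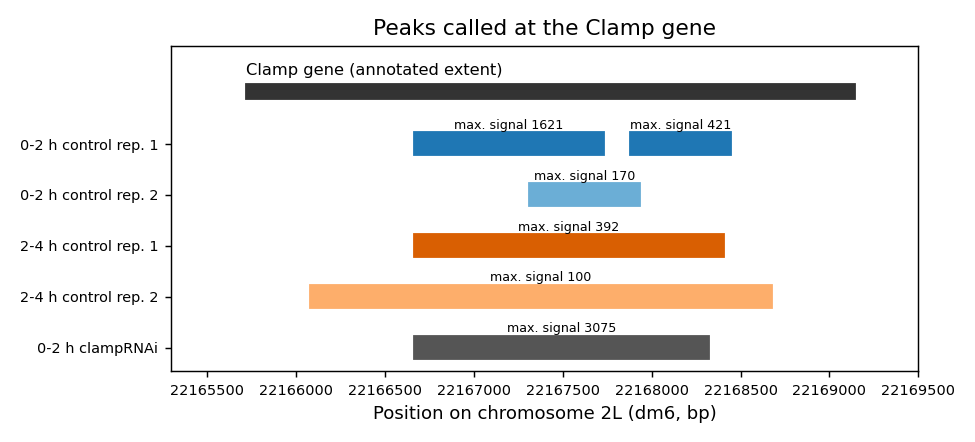
Peaks called at the Clamp gene on 2L, with position in dm6 base pairs on the x axis, the annotated gene extent as the dark bar and 1 line of peaks per library below it, each labelled with its maximum signal. Peaks lie within the gene in all 5 libraries, with maximum signals from 100 in 2-4 h replicate 2 to 3075 after clampRNAi.

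Called peaks were concentrated on the X chromosome in every library, although the embryos were female. No library without the antibody was used here, so MLE binding was not separated from nuclease background or from repeat sequence on X. X held 44.7% of main-arm peaks in both 0-2 h controls (Wilson 95% intervals 40.8% to 48.7% and 41.8% to 47.7%), 49.8% (44.5% to 55.2%) and 31.2% (28.5% to 34.0%) in the 2-4 h controls and 47.8% (43.1% to 52.5%) after clampRNAi, while X made up 17.6% of the sequence of those arms. The excess was 2.54-fold in both 0-2 h controls, 2.83-fold and 1.77-fold in the 2-4 h controls and 2.72-fold after clampRNAi. It passed an exact binomial test in all 5 libraries, with the largest adjusted p = 4.2e-28. Peak density on X was 11.3 and 20.5 per Mb in the 0-2 h controls, 6.97 and 14.6 in the 2-4 h controls and 8.79 after clampRNAi, and X was the densest arm in 4 libraries. Chromosome 4 was denser in 2-4 h replicate 2, at 17.4 per Mb, and held 12.1 per Mb in 0-2 h replicate 2, where 2L, 2R, 3L and 3R held 4.04 to 6.24.

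Peaks of both width classes shared the X excess. Of peaks under 200 bp, 47.7%, 48.8%, 49.1% and 48.2% lay on X in the control libraries and 48.1% after clampRNAi, and of wider peaks 37.1%, 35.8%, 53.3% and 29.3% in the controls and 46.6% after clampRNAi. The X share was 44.7% ± 0.0116 (SD, n = 2) at 0-2 h and 40.5% ± 13.2 (SD, n = 2) at 2-4 h (exact permutation p = 1). With 2 against 2 libraries the smallest possible p is 0.333, so this test could not have passed the threshold. Within replicate 1 the 2-4 h share was 5.14 percentage points higher than at 0-2 h, and within replicate 2 it fell by 13.5 points. Unplaced X sequence lies off the main arms and is left out of these shares. It held 48 and 56 peaks in the 0-2 h controls, 6 and 329 in the 2-4 h controls and 12 after clampRNAi. In 2-4 h replicate 2, 329 of the 487 off-arm peaks were thus on X sequence, against 344 peaks on the X arm. The lower X share of that library therefore holds for the main arms alone.

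**Figure D3:**
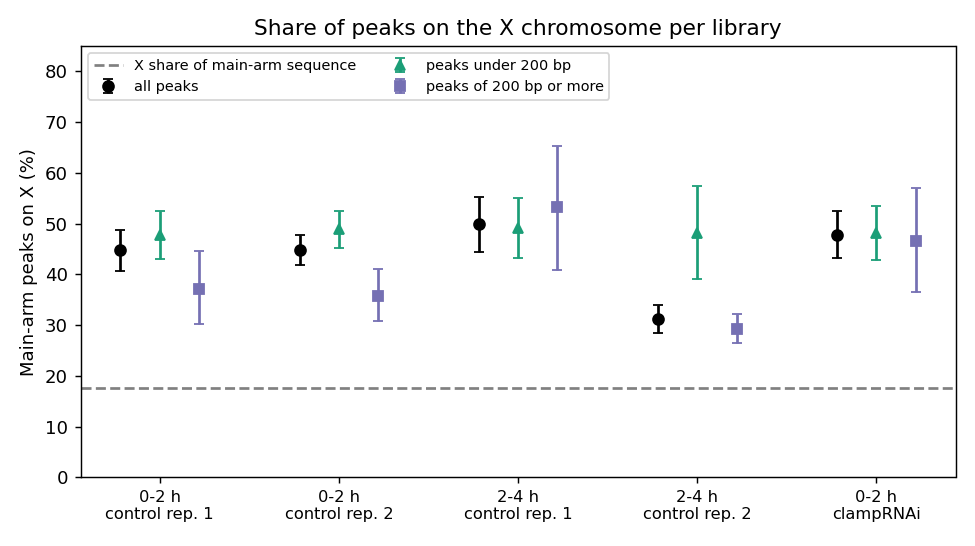
Share of main-arm peaks on the X chromosome (y axis, percent) in each of the 5 libraries (x axis), for all peaks (circles), peaks under 200 bp (triangles) and peaks of 200 bp or more (squares), with Wilson 95% intervals that cover counting error only. Every point lies above the dashed line at 17.6%, the share of main-arm sequence on X, and the lowest of the circles is 2-4 h replicate 2 at 31.2%.

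Most genes of dosage compensation and female sex determination carried no peak, and neither list passed the test in any library. The roX genes on X encode the non-coding RNAs of the dosage compensation complex: roX1 (3857230 to 3862697) had no peak in any library, and roX2 (11579065 to 11580432) had a peak in 2-4 h replicate 1 alone, at 11578766 to 11579124, with a maximum signal of 115 and a percentile of 45.4. Sxl, the female switch gene (X, 7074550 to 7098053), its target tra (3L, 16590059 to 16591050), msl-2, which encodes a complex subunit made in males (2L, 3462218 to 3466112), and mle itself (2R, 5974857 to 5980778) had no peak in any library. Of 9 dosage compensation genes, Clamp was the only one with a peak in 4 libraries, and Clamp and roX2 had peaks in 2-4 h replicate 1. The counts of 1, 1, 2, 1 and 1 genes in the 5 libraries lay above the 0.157, 0.273, 0.109, 0.449 and 0.114 of matched lists, with a smallest adjusted permutation p = 0.0541 in 2-4 h replicate 1. Of 18 sex determination genes, only fru, which directs male courtship circuits, had peaks, in the 0-2 h controls.

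Peaks lay inside genes and away from gene ends. Within 500 bp of an annotated gene start or end lay 12.6% and 13.4% of peaks in the 0-2 h controls, 12.8% and 14.8% in the 2-4 h controls and 12.01% after clampRNAi, against 17.2% to 17.5% of placements (permutation of peak positions, adjusted p between 0.00428 and 0.0415). Farther inside genes lay 66.6%, 64.7%, 68.4% and 69.3% of peaks in 0-2 h replicates 1 and 2, 2-4 h replicate 1 and clampRNAi, above placements (58.7% to 59.0%, adjusted permutation p = 0.00428 in each). In 2-4 h replicate 2 the inside share, 53.8%, was below placements (57.8%, adjusted permutation p = 0.0136) and the intergenic share, 31.4%, above them (24.6%, adjusted permutation p = 0.00428). Among peaks of at least 200 bp, 0 libraries passed the test for fewer peaks near gene ends and 0 for more peaks inside genes, and with every list kept to 370 peaks 1 library passed for gene ends.

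Among 16 gene lists, small structural RNA genes and histone genes stood apart from random gene lists matched on length and coding type. A cluster of U6 genes, which encode a spliceosomal RNA, had a peak in every library: snRNA:U6:96Aa, snRNA:U6:96Ab and snRNA:U6:96Ac on 3R were covered by a single peak of 1242 bp, 1246 bp, 1245 bp and 1689 bp in the control libraries and 1243 bp after clampRNAi. In 0-2 h replicate 1 the peak ran from 24556085 to 24557326, and the genes ran from 24556088 to 24557321. In all, 3, 5, 3 and 8 of 32 snRNA genes had a peak in the control libraries and 3 after clampRNAi. The count passed the permutation test in 0-2 h replicate 2 (adjusted p = 0.00457) and both 2-4 h controls (0.0464 and 0.0284), where matched lists held 0.567, 0.346 and 2.44, and not in 0-2 h replicate 1 (0.399) or clampRNAi (0.0541). The U6 genes are near-identical copies within 1 peak, and by separate loci 1, 2, 1, 5 and 1 of 21 held a peak in the 5 libraries. Without rRNA genes in the background the snRNA count passed in all 5 libraries, and with every list kept to 370 peaks it passed in 0-2 h replicate 2 alone.

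Replication-dependent histone genes had broad peaks in 3 libraries, which were low within their lists in the 0-2 h controls only. Of 111 genes of the 2L array (21416953 to 21541681), 13 and 44 had a peak in the 0-2 h controls, 0 and 111 in the 2-4 h controls and 0 after clampRNAi. The count passed the permutation test in both 0-2 h controls and 2-4 h replicate 2 (adjusted p = 0.0032 in each), where matched lists held 0.833, 2.72 and 8.02. Peaks covered 97.0% of the array in 2-4 h replicate 2, with a maximum signal of 66 against a list median of 53. In the 0-2 h controls they covered 6.86% and 20.4%, with maximum signals of 20 and 15 against list medians of 388 and 309. His1:CG33834, His2A:CG33835, His2B:CG33888 and His4:CG33887 had a peak in each of these 3 libraries. The repeats are near-identical copies, so reads from 1 repeat can be placed on another, and the array counts as 2 loci. With every list kept to 370 peaks, or to its upper 50% by signal, 0 of these genes had a peak in the 0-2 h controls, and the call was left in 2-4 h replicate 2 alone.

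Transfer RNA and small nucleolar RNA genes held few peaks. Of 290 tRNA genes, 2 and 0 had a peak in the 0-2 h controls, 0 and 4 in the 2-4 h controls and 0 after clampRNAi, with fewer than in matched lists in 0-2 h replicate 2 and 2-4 h replicate 2 (adjusted permutation p = 0.0032 in both). The 4 in 2-4 h replicate 2 included tRNA:Asp-GTC-1-11, whose peak within 500 bp was that of the U6 genes. Of 269 snoRNA genes, none had a peak outside 2-4 h replicate 2, which had 11, and the count was lower than in matched lists in both 0-2 h controls (adjusted permutation p = 0.00457 and 0.0284). Short non-coding strata hold many 5S rRNA genes, and without rRNA genes in the background neither snoRNA call was left (adjusted permutation p = 0.73 and 0.092), while both tRNA calls were. With every list kept to 370 peaks, the tRNA call in 2-4 h replicate 2 was the only lower call left.

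No embryonic patterning list passed the test in any library. Of 22 gap and pair-rule genes, the zinc finger gene opa (3R) had a peak in all 5 libraries at percentiles of 82.1 to 89.6, 72 to 190 bp wide in 4 of them and 1495 bp in 2-4 h replicate 2. The repressor gene hry (3L) had a 40 bp peak in 0-2 h replicate 1 and clampRNAi and a 36 bp peak in 2-4 h replicate 1. Of 8 Hox genes, Abd-B had a peak in all 5 libraries, Antp in the 0-2 h controls and clampRNAi, and Ubx in 2-4 h replicate 2. Of 29 early zygotic genes only the T-box gene Doc1 had a peak, in 2-4 h replicate 2, and of 18 maternal and germ plasm genes zld, the early genome activator, and osk had 1 library each.

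Regulators of chromatin and splicing did not stand apart from matched lists either. Of 28 splicing factor genes, Rbfox1 had a peak in all 5 libraries, mub in 3, bru1 in 3 and ps in 2, the ps peaks lying at percentiles of 97.7 and 98.2 in the replicates 2. Of 19 chromatin regulators and GA binders, 2, 3, 2 and 3 had a peak in the control libraries and 2 after clampRNAi, among them Clamp in all 5 and psq, which encodes another GA-binding protein, in 4. Hsp68 was the only 1 of 16 heat shock genes with a peak, in 2-4 h replicate 2, and of 82 ribosomal protein genes RpL32 had peaks in both replicates 2 and RpL7A and RpL22 in 2-4 h replicate 2. Among lists for other cell types, 0 of 13 eggshell genes of follicle cells and 0 of 16 testis genes had a peak in any library. Over the 5 libraries, 6 tests of a gene list found more genes with a peak than matched lists and 4 found fewer, and with every list kept to 370 peaks these numbers were 2 and 1.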

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

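The embryos were bred to be female, and peaks on the Y chromosome had no comparison of their own. They were left out of the main-arm comparisons but are included in the counts of merged regions. They numbered 17 and 21 in the 0-2 h controls, 17 in 2-4 h replicate 2 and 10 after clampRNAi, above the 3 that a count of 0 allows, while 2-4 h replicate 1 had 3. That limit covers counting error only and is not a measured background. Their median width was 489 bp, 464 bp, 543 bp and 522.5 bp in those 4 libraries. The peaks formed 28 regions, of which 14 were called in both 0-2 h controls and 3 in all 5 libraries. No explanation for them was tested.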

How the results depend on the processing

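Peaks of at least 200 bp only and the background without rRNA genes were chosen after seeing the data, as were all contigs and the removal of centromeric ends. The X excess kept its direction in all 5 libraries under every alternative run for it and passed the test under each that was tested, and the 4 overlaps tested under alternatives stayed above placement. Their size moved: at 2-4 h the replicate overlap (76.6%) was 24.3% with equal list lengths and 20.7% with reciprocal overlap, and with peaks of at least 200 bp that at 0-2 h (88.1%) was 44.9%, 2-4 h replicate 1 in 0-2 h replicate 1 (98.8%) was 63.3% and clampRNAi in 0-2 h replicate 1 (98.2%) was 64.8%. Counts by stage and by clampRNAi depended on list length and width, and the cause was not tested except where stated.

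Regions called in both 2-4 h and neither 0-2 h control (0) became 2 with equal list lengths, 6 with peaks of at least 200 bp and 4 with reciprocal overlap, and ranged from 0 to 941 when 1 library was left out, the highest without 2-4 h replicate 1. Regions called in both 0-2 h and neither 2-4 h control (165) became 89 in the upper 50% of each list, 2 with equal list lengths and 21 with peaks of at least 200 bp, and ranged from 231 to 527, the highest without 0-2 h replicate 1 (255 without 2-4 h replicate 2). A left-out library removes a condition from the definition, which by itself favours higher counts. The share of 0-2 h regions called after clampRNAi (76.6%) was 72.0% in the upper 50%, 93.0% with equal list lengths, 60.8% with peaks of at least 200 bp, 80.7% on main arms and 68.4% with reciprocal overlap, and ranged from 38.5% to 66.5% without a 0-2 h library. The number not called (141) became 91, 16 and 60 under the first 3 of these and ranged from 234 to 751, the highest without 0-2 h replicate 1.

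By covered bases the X share was 39.1% and 32.0% in the 0-2 h controls. The stage difference in X share (-4.18 points) reversed to 4.86 with peaks of at least 200 bp and ranged from -13.5 to 5.13 when 1 library was left out, the reversal being without 2-4 h replicate 2. Libraries with fewer peaks near gene ends (5) became 1 in the upper 50%, 1 with equal list lengths, 1 within 200 bp of gene ends and 0 with peaks of at least 200 bp, where libraries with more peaks inside genes (4) also became 0. With those wider peaks the direction reversed inside genes in 0-2 h replicate 1 (55.1% against 58.3%) and 2-4 h replicate 1 (58.3% against 59.6%) and between genes in 2-4 h replicate 1 (25.0% against 23.3%) and clampRNAi (26.1% against 23.9%). The share between genes also moved from below to above placement in 0-2 h replicates 1 (28.7% against 24.4%) and 2 (26.7% against 24.4%), where neither value passed the test, and near gene ends it reversed in 2-4 h replicate 2 with equal list lengths (17.9% against 17.1%). Gene list tests with more genes (6) became 2 in the upper 50% and 2 with equal list lengths, and those with fewer (4) became 2, 1 and, without rRNA genes, 2. Among the values not tied to a comparison, 129 kept their side of the threshold, 48 no longer passed it and were not counted as reversed, 8 newly passed it, and 5 reversed and no longer passed it. By a rule added after seeing the data, a list with 0 genes and under 1 expected has no direction. The 48 thus include the histone genes of both 0-2 h controls in the upper 50% and with equal list lengths, which fell from above expectation to 0 genes.

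Pairing by replicate number as a block gave the same counts, 0 and 165, by construction. Deviations of same-numbered libraries correlated at 0.365 over 275 regions, a value that is equal for both numbers with groups of 2, and 2 pairs are too few to take the numbers as a pairing. Overlap tests already used main arms only, and the motif alternatives were not run. Depth is unknown, so a region not called may lie just under a list's threshold. With equal list lengths 93.0% of 227 regions of both 0-2 h controls were called after clampRNAi. The share was lower in the upper 50% (72.0%), with peaks of at least 200 bp (60.8%) and with reciprocal overlap (68.4%).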

Other observations

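The hypothesis on dpr and DIP genes and the tests of library batches, of maternal CLAMP on X and of CLAMP loss were chosen after the results were seen, as were the genes pan and CG42699. The 5S rRNA genes, 96 copies in an array on 2R (19729562 to 19766278), held peaks in all 5 libraries. Peaks touched 16 and 6 of the copies in the 0-2 h controls, 5 and 30 in the 2-4 h controls and 5 after clampRNAi, and covered 13.2%, 2.71%, 2.24%, 25.0% and 2.25% of the array. The copies are near-identical, so the position within the array is uncertain. The mitochondrial genome held 6 and 1 peaks in the 0-2 h controls, 4 and 1 in the 2-4 h controls and 4 after clampRNAi. Unplaced X sequence held 48, 56, 6, 329 and 12 peaks in the same order.

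At single loci the authors' maximum signal, on scales of unknown depth, took very different values. In pan, the gene of the Wnt pathway transcription factor TCF, a peak on chromosome 4 starting between 98119 and 98128 had a maximum signal of 356 and 243892 in the 0-2 h controls, 126 and 257999 in the 2-4 h controls and 181 after clampRNAi. At CG42699 on X the values were 8508 and 56, 39173 and 140, and 64805.

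Cell-surface proteins of the dpr and DIP families pair neurons, and dpr2, dpr8, dpr16, DIP-alpha and DIP-beta each had a peak in all 5 libraries. The hypothesis that these families hold peaks more often than other genes of their length was not borne out. Of 32 family genes, 7 and 9 had a peak in the 0-2 h controls, 6 and 7 in the 2-4 h controls and 7 after clampRNAi, against 4.51, 6.77, 2.99, 6.61 and 3.79 in matched lists, and the excess passed the test in 0 of 5 libraries (smallest adjusted permutation p = 0.338).

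X held more peaks than its length in all 5 libraries. Narrow pile-ups as the whole cause were argued against by peaks of at least 200 bp that touched no narrower peak, whose lowest X share was 23.2% against 17.6% of sequence, and a concentration near centromeres by a lowest share of 31.2% without 3 Mb at the centromeric ends. A part played by maternal CLAMP stays open with 1 depleted library, whose X share was 47.8%. Binding of MLE in females also remains open, as do repeat sequence on X and a background of the nuclease, since neither genome sequence nor a library without the antibody was used here.

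Regions called in only 1 pair of the control libraries divided by replicate number more than by stage, while pairwise similarity was mixed. List length as the whole cause was argued against, since with equal lists 106 regions were in both replicates 2 and neither replicate 1, and 94 in both replicates 1 and neither replicate 2, against 2 and 2 by stage. A difference between library batches is a candidate explanation. Among the 50 peaks with most signal in 0-2 h replicate 2, 50 were called in 2-4 h replicate 2, 22 in 0-2 h replicate 1 and 17 after clampRNAi. These counts show the same split in the strongest peaks and cannot tell a batch from another cause of it. The strongest peaks of 0-2 h replicate 1 showed no such division, with 49 of 50 called in 2-4 h replicate 1 and 50 in both replicates 2, and 2-4 h replicate 2 is the longest and widest list. The series' design text names several batches of crosses, the labels assign no library to them, and a difference in the embryos collected remains untested.

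Of the 602 regions of both 0-2 h controls, 141 were not called after clampRNAi. A shorter clampRNAi list, loss of maternal CLAMP and the division by replicate number cannot be told apart here. Over covered bases, the clampRNAi list had Jaccard indices of 37.4% and 51.1% with the 0-2 h and 2-4 h replicates 1. With the replicates 2 they were 16.4% and 1.58%, although those lists are longer. When 0-2 h replicate 1 was kept to the length of the clampRNAi list, 87.8% of its peaks were called there (84.6% to 90.6%), against 20.9% of its remaining peaks, and the interval includes the 90% set in advance as the bound. A control library with maternal CLAMP and a shorter list, 2-4 h replicate 1, called 2 of the 141, but it differs in stage and is 1 library. Further clampRNAi libraries would be needed to separate these.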
